A study of Mus musculus with 5 samples.

How the data were processed

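Messenger RNA levels were measured by RNA sequencing in keratinocytes isolated from the back skin of mice at 28 days of age. Per the labels, cells were either sorted for GFP and described as Lrig1 positive keratinocytes (3 libraries, GFP replicates 1, 2 and 3) or taken as the entire basal keratinocyte population without that sort (2 libraries, bulk replicates 1 and 2). The labels give bulk samples a wild-type genotype and sorted samples an Lrig1 positive genotype, although bulk and GFP libraries share title numbers. The reporter construct and the gates are not given in the sources used here.

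The deposited table holds whole-number counts per versioned Ensembl mouse gene ID, 1 column per library, with no normalization. Per the submitters' processing notes, STAR and the genome build GRCm39 were used. Versions, the counting tool, the annotation release, strandedness and filters are not given in the sources used here. Without stated strandedness, counts of overlapping or antisense genes could not be separated, and counts of near-identical copies such as the alpha globin pair Hba-a1 and Hba-a2, the hair keratins and the keratin-associated proteins depend on how shared reads were assigned. Symbols were taken from the GENCODE mouse M21 annotation, which is on an earlier build (GRCm38), by gene ID without its version: 52073 of 56691 IDs matched and 4618 did not. No coordinates are given because the builds differ.

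Total counts were 56829330 and 105887450 in bulk replicates 1 and 2, and 85307002, 71410484 and 89080100 in GFP replicates 1, 2 and 3. At this depth 18583 genes passed edgeR's filterByExpr (minimum count 10, minimum total count 15) and held at least 99.9 percent of the counts in each library, while 23876 genes had no count in any library. The deposited counts carry no molecular identifiers. The p-values depend on the spread between these libraries and, for genes with few counts, also on read numbers. The labels do not state that the libraries of a group come from separate animals.

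The comparison was made with edgeR 4.0.16 in R 4.3.3, using TMM scaling, a group term and the quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. This design leaves 3 residual degrees of freedom. Levels are CPM (counts scaled to the same library size, TMM-adjusted), given as mean ± SD, and log2 fold changes (GFP over bulk) are given ± SE. The 27 gene lists were tested with camera of limma 3.58.1 at its preset correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the 27 lists. Camera at an estimated correlation rests on the 3 residual degrees of freedom and so had little power. A list it did not call is not shown to be unchanged. The lists share some members, among them Shh, Lef1 and Fst, and so are not independent of each other. The test, the lists, the rule for named genes and the alternatives below were fixed before the data were examined. The rule named Lrig1, the 10 called genes with the largest rise and the 10 with the largest fall (mean log2 CPM of at least 3, libraries of the groups not overlapping, no predicted models or pseudogenes), up to 4 members of each list with the smallest p, and the 5 most abundant genes of each group. Some of the genes so named are not reported here. The alternatives were DESeq2 1.42.0 size factors, upper quartile scaling, library size alone, the DESeq2 Wald test, limma-voom, other filters on low counts, robust dispersion, a test against a 1.5-fold change, removal of mitochondrial and haemoglobin genes, a replicate block, and leaving out each library in turn.

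Title numbers are shared by bulk 1 and GFP 1 (4143) and by bulk 2 and GFP 2 (4145), while GFP 3 has its own number (4146). They were taken to name the animal, which the labels do not state, before calls with and without a block were compared. Across genes, the difference of bulk 1 and bulk 2 correlated with the difference of GFP 1 and GFP 2 (Pearson r = 0.474, genes not being independent replicates). A fit with the number as a block uses 2 pairs, gains nothing from GFP 3 and has 1 residual degree of freedom. Replicates of a group differed by far more than sampling noise (chi-square per degree of freedom 91.5 to 279.9), so none were treated as the same library.

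The ratio of libraries varied with gene length in the 8 pairs compared, with a Spearman rho across genes from -0.532 to 0.593 and the weakest at -0.124 (GFP 3 over bulk 2). A correction was therefore added after seeing the data: a loess trend (span 0.3) of each library's log2 CPM on length and GC content, from the longest M21 transcript of each gene, entered the fit as an offset. Of the tested genes, 18107 (97.44 percent) had a length, and the 476 without one were left out of this fit. The edgeR test was tested on simulated data, with counts drawn from the means and dispersions of this comparison for 17883 genes. It recovered 7.292 percent of genes changed 2-fold and 56.84 percent of genes changed 4-fold, with 6 false calls among 67. Only 96 genes changed 2-fold and 95 changed 4-fold were in it, while 982 genes were called in the data. With so few changed genes the adjusted p set a stricter cutoff than in the data. The recovered shares are therefore not the power of the comparison itself. A list raised 1.5-fold was recovered by camera (adjusted p = 1.77e-16), with 1 other list of 27 called. Genes were drawn independently of each other in this simulation. It therefore cannot show how often camera at its preset correlation of 0.01 calls correlated lists falsely. In the data the estimated correlation was 0.647 for the Langerhans cell and myeloid list. In a simulation of the blocked fit over 17725 genes with a length and GC trend in the libraries, 1191 of 1343 calls were false when the trend was kept and 7 of 157 when it was removed. The trend was put in and taken out by the same loess function, so its removal was bound to work. Apart from the genes changed on purpose, all of the trend counted as false. The simulation cannot show whether the removal also takes out differences between the populations. Figures were drawn with matplotlib 3.10.9, and permutation tests used scipy 1.17.1.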

Results

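Gene expression was compared between keratinocytes sorted for GFP from back skin of mice at day 28 and cells labelled as the entire basal keratinocyte population. Lrig1, the gene that gives the sorted cells their label, encodes a membrane protein that restrains receptors of the EGF family and marks cells of the upper hair follicle. There were 3 GFP-sorted and 2 bulk libraries, with 56829330 to 105887450 counts each. The question was how the cells labelled Lrig1 positive differ from the bulk population. The labels do not show that the sorted cells came from these bulk populations, and GFP replicate 3 has no bulk library of its title number. Although labelled basal, bulk libraries 1 and 2 held 36090 and 29750 CPM (library size scaling) of suprabasal list genes. Genes of the basal layer list summed to 21860 and 25400 CPM there. GFP replicates 1, 2 and 3 held 11250, 16040 and 13960 CPM of the suprabasal list and 35960, 31330 and 34480 CPM of the basal list. Such sums do not measure shares of cells. GFP replicate 3 was the only library with abundant Xist, the transcript that silences an X chromosome in females. It had 53714 Xist counts, against 0 to 8 in the other 4 libraries. It had 62 counts of the Y-linked gene Ddx3y, against 1750 to 4462. The labels give no sex. By this pattern only the sorted group held a female library, so sex was not balanced between the groups.

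GFP-sorted cells carried less RNA of genes of hair shaft and inner root sheath, of melanocytes, immune cells and red blood cells, and of part of the cornified epidermis than the bulk population. The lists for these were called lower by camera at its preset correlation and not with an estimated correlation (smallest adjusted p = 0.0954). The latter test had little power at 3 residual degrees of freedom. The hair keratin gene Krt81 was at 34.4 ± 3.26 CPM in bulk and 0.0479 ± 0.0254 CPM in GFP-sorted cells (mean ± SD, n = 2 and 3). Rises were fewer and smaller, and included the EGF receptor ligand Epgn, at 276 ± 65.9 CPM in bulk and 873 ± 234 CPM in sorted cells. Epgn was not called without GFP replicate 2 (edgeR adjusted p = 0.0545) or with the length and GC trend removed. Nor did its call hold without bulk replicate 1 or bulk replicate 2 (log2 changes of 1.44 and 1.91), fits that leave 1 bulk library. Keratins and adhesion genes of the basal layer were called higher as a list by camera at its preset correlation, but not with an estimated correlation (adjusted p = 0.353) or by fry (0.0931). No single member passed the test. Of 18583 genes tested with edgeR, 982 were called at an adjusted p under 0.05 (Benjamini-Hochberg), 955 lower and 27 higher in sorted cells. With the replicate number as a block, 6692 were called, 3652 lower and 3040 higher, and these included all 982. With the replicate block and the length and GC trend of the libraries removed, 5578 were called, 3892 lower and 1686 higher. In that fit the median log2 change of all genes was -0.112, against 8.32e-05 with the block alone. The split into lower and higher calls carries this shift.

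Lrig1 itself (ENSMUSG00000030029.15) was at 159 ± 5.82 CPM in bulk (n = 2) and 216 ± 8.75 CPM in sorted cells (n = 3). The log2 difference of 0.44 ± 0.18 was not called by edgeR (adjusted p = 0.292). It was called with the replicate block (0.45, adjusted p = 0.00676 in edgeR). All 3 sorted libraries lay above both bulk libraries. As the labels describe the sorted cells as Lrig1 positive, the value checks the labels and is not a finding.

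Genes of the hair matrix and inner root sheath, the cells that build the growing hair, fell almost throughout. Of 17 tested members 16 fell, also when adjusted over the list alone, with a list median of -5.44. Krt25, Krt27 and Krt28, keratins of the inner root sheath, fell by 5.48 ± 0.33, 6.63 ± 0.47 and 4.31 ± 0.31 on the log2 scale (edgeR adjusted p = 1.64e-04, 2.97e-04 and 2.97e-04). The hair cortex keratin Krt31 fell by 6.74 ± 0.39. The exception was the transcription factor gene Gata3, with a log2 change of -0.47 (edgeR adjusted p = 0.444, and 0.0216 with the replicate block and the length and GC trend kept), a gene singled out after its values were seen. The list was lower by camera (adjusted p = 1.35e-69; adjusted p = 0.0954 with an estimated correlation).

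Among genes with a mean log2 CPM of at least 3, predicted models aside, the 10 largest falls included Gprc5d, a receptor gene of hair-forming cells, and the hair keratins Krt81, Krt33b, Krt83 and Krt87. The others were the keratin-associated proteins Krtap8-1, Krtap11-1 and Krtap7-1, and the cornified layer genes Hrnr and Flg2. Their log2 changes ran from -9.69 ± 0.41 for Gprc5d to -6.92 ± 0.61 for Flg2. All 10 remained called in every alternative run.

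Of 23 genes of suprabasal differentiation, 10 fell and none rose. Adjusted over the list alone 15 fell, and with the replicate block 20 fell, or 22 with the length and GC trend also removed. On the log2 scale Lor, a main protein of the cornified envelope, fell by 5.37 ± 0.26. The desmosome genes Cdsn and Dsc1 fell by 3.74 ± 0.33 and 2.14 ± 0.20. Krt10, the early suprabasal keratin, was at 11621 ± 2704 CPM in bulk and 5718 ± 1290 CPM in sorted cells, which did not pass (edgeR adjusted p = 0.174, and 7.88e-06 with the replicate block and the trend kept). The list was lower by camera (adjusted p = 3.6e-21; adjusted p = 0.0954 with an estimated correlation).

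In the sebaceous gland list, 5 of 17 fell and none rose. There were 8 falls adjusted over the list alone, and with the replicate block 8 fell and 3 rose. None of the 3 rises stayed, and 10 fell, with the block and the length and GC trend removed. Without bulk replicate 1 only 2 fell, and without bulk replicate 2 only 3. The lipid enzymes Soat1 and Dgat2 fell by 3.01 ± 0.24 and 1.42 ± 0.22 on the log2 scale, Dgat2 not without bulk replicate 1 (edgeR adjusted p = 0.0767). The list was lower by camera (adjusted p = 1.56e-04; adjusted p = 0.385 with an estimated correlation). Of 20 cholesterol synthesis genes, Lss fell by 1.13 ± 0.23 and no other was called. Lss was not called without bulk replicate 1, bulk replicate 2 or GFP replicate 1 (edgeR adjusted p = 0.13, 0.157 and 0.0625), and 2 genes of this list fell without GFP replicate 2. There were 5 falls adjusted over the list alone, and 12 with the replicate block. Camera called this list lower (adjusted p = 0.00828; adjusted p = 0.5 with an estimated correlation). It did not without bulk replicate 2 (0.0533) or GFP replicate 1 (0.0864).

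**Figure D1:**
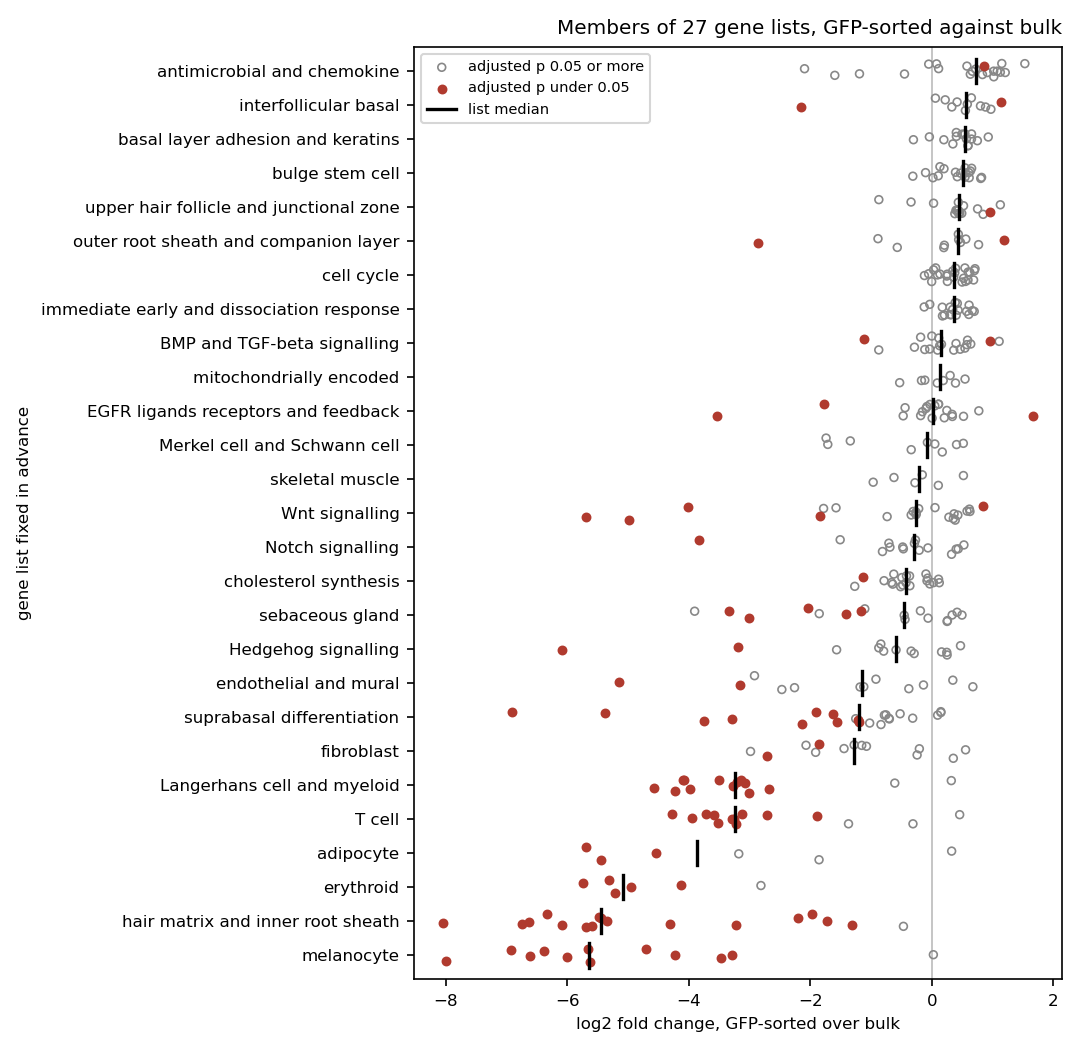
Log2 fold change (GFP-sorted over bulk, x axis) of every tested member of the 27 gene lists (y axis), each point a gene, filled where the edgeR adjusted p was under 0.05, with a bar at the list median. The medians run from -5.64 for melanocyte genes to 0.72 for antimicrobial and chemokine genes, and the filled points lie almost all to the left of 0.

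Markers of melanocytes, immune cells and red blood cells were lower in sorted cells. In the melanocyte list 11 of 12 genes fell, also adjusted over the list alone. The pigment enzyme gene Dct fell from 70.8 ± 48.2 CPM to 1.40 ± 0.54 CPM, and the receptor gene Kit fell by 4.23 ± 0.30 on the log2 scale. The list was lower by camera (adjusted p = 6.06e-28; adjusted p = 0.0954 with an estimated correlation). In the Langerhans cell and myeloid list 12 of 14 fell, also adjusted over the list alone. Laptm5 fell by 4.23 ± 0.26 and the antigen presentation gene H2-Eb1 fell by 3.14 ± 0.31 (camera adjusted p = 2.3e-28 for the list; adjusted p = 0.134 with an estimated correlation). In the T cell list 11 of 14 fell, and camera called it lower (adjusted p = 8.34e-29; adjusted p = 0.0954 with an estimated correlation). Cd3e, part of the T cell receptor complex, was at 16.8 ± 2.99 CPM in bulk and 1.94 ± 0.53 CPM in sorted cells. Adjusted over the list alone 12 T cell genes fell and Thy1 rose, with 133 CPM in bulk and 182 CPM in sorted cells. Thy1 was singled out after its values were seen. Over all genes it was called with the replicate block (edgeR adjusted p = 0.0155, against 0.282) and not with the block and the length and GC trend removed (0.545). Of 6 red cell genes 5 fell, and 6 adjusted over the list alone. Hba-a1, an alpha globin gene, fell by 4.95 ± 0.57 (camera adjusted p = 1.18e-14 for the list; adjusted p = 0.103 with an estimated correlation).

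Of 13 fibroblast genes Dcn and Pdgfra fell. Dcn was not called without bulk replicate 1 (edgeR adjusted p = 0.0894), and Pdgfra not without bulk replicate 2, GFP replicate 1 or GFP replicate 2 (0.504, 0.098 and 0.0535). In this list 4 genes fell without GFP replicate 1, and 1 without bulk replicate 2 or GFP replicate 2. Adjusted over the list alone 3 fell, and with the replicate block 9 fell and 1 rose, the rise being lost when the trend was also removed. Camera called the list lower (adjusted p = 0.00932; adjusted p = 0.353 with an estimated correlation), but not with the length and GC trend removed (0.161). The list median was -0.24 for GFP 1 against bulk 1 and -1.95 for GFP 2 against bulk 2. Of 12 endothelial and mural genes Tie1 and Cldn5 fell. Neither was called without bulk replicate 1 (edgeR adjusted p = 0.0843 and 0.123) or bulk replicate 2 (0.066 and 0.0929). There were 6 falls adjusted over the list alone, and with the replicate block 7 fell and 1 rose. These genes lay near the floor. The list summed to 13.37 and 13.24 CPM in bulk 1 and 2 (library size scaling). It summed to 13.48, 9.718 and 5.961 CPM in GFP 1, 2 and 3. With a minimum of 1 CPM 4 of its genes were tested and 0 called. The list was lower by camera (adjusted p = 0.00228; adjusted p = 0.353 with an estimated correlation), but not with the replicate block, with the trend kept (0.0686) or removed (0.133). Of 6 adipocyte genes 3 fell, 4 adjusted over the list alone, and with the replicate block 5 fell and 1 rose. With a minimum of 1 CPM 2 were tested and 1 fell. Only 1 fell without bulk replicate 1, 1 without bulk replicate 2, and 2 without GFP replicate 2 or 3. Fabp4, a fatty acid carrier, fell by 5.69 ± 0.79 (camera adjusted p = 3.93e-04 for the list; adjusted p = 0.353 with an estimated correlation). edgeR called none of 6 skeletal muscle genes, with 0 at an unadjusted p under 0.05 and 0 called by DESeq2 or limma-voom. edgeR also called none of 9 Merkel and Schwann cell genes over all genes, and 2 lower adjusted over the list alone. For these 9, 2 were lower at an unadjusted p under 0.05, DESeq2 called 2 lower and limma-voom 0, and the replicate block gave 2 lower and 2 higher, or 2 lower and 0 higher with the trend removed. Without GFP replicate 3, 1 was lower. Neither list was called by camera (adjusted p = 0.89 and 0.447).

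**Figure D2:**
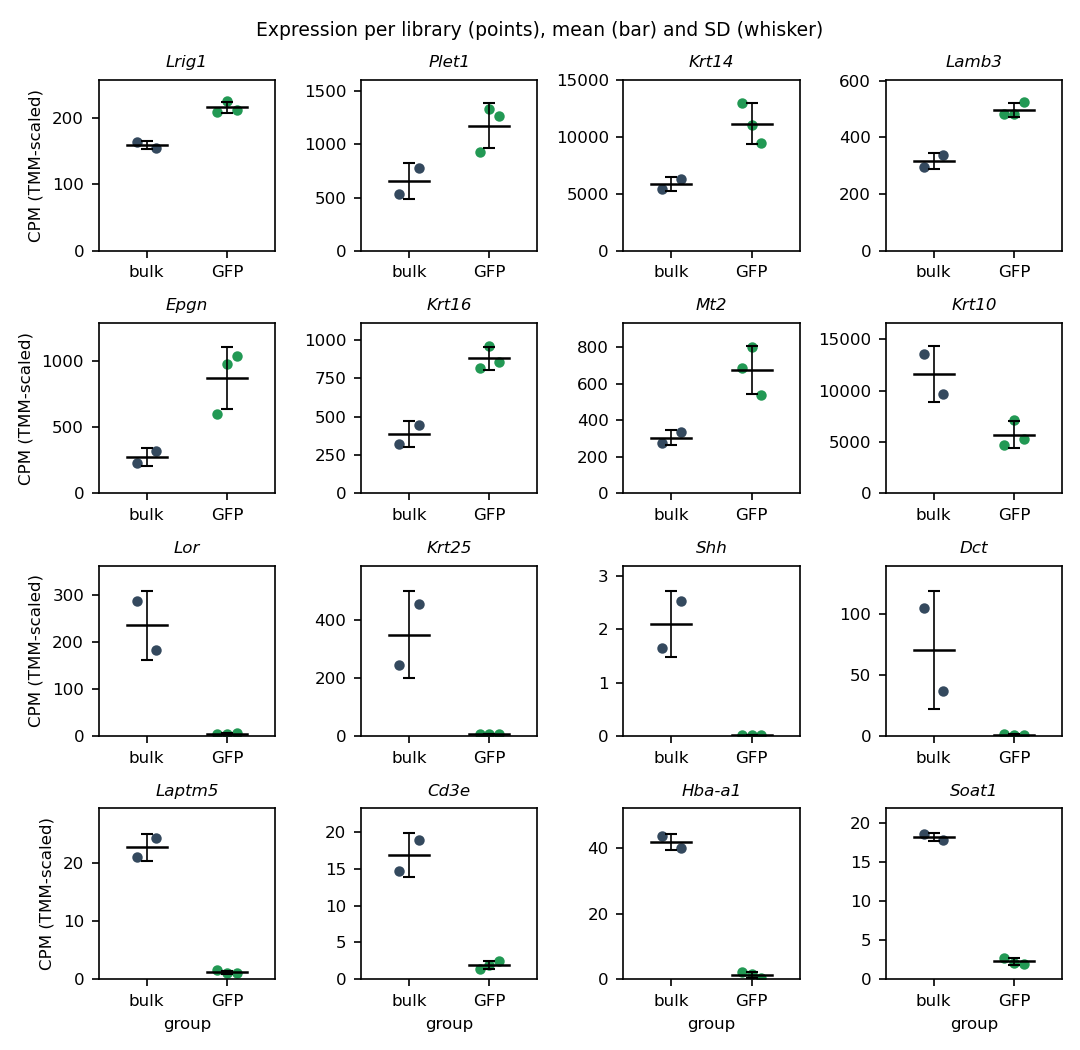
TMM-scaled CPM (y axis) of 16 genes in the 2 bulk and 3 GFP-sorted libraries (x axis), each point a library, with the mean as a bar and the SD as a whisker. Lrig1, Plet1, Krt14, Lamb3, Epgn, Krt16 and Mt2 lie higher in sorted cells, and the other 9 lie lower, with Cd3e at 16.8 CPM in bulk and 1.94 CPM in sorted cells.

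Among 23 Wnt genes Lef1, Nkd1, Notum and Nkd2 fell, the last by 4.02 ± 0.47, and the ligand gene Wnt10a rose by 0.84 ± 0.19. Nkd1 was not called without bulk replicate 1 (edgeR adjusted p = 0.0698). Wnt10a was singled out after its values were seen. No Wnt gene was called higher without bulk replicate 1, bulk replicate 2, GFP replicate 1 or GFP replicate 2, with library size alone, with a minimum of 1 CPM, or with the length and GC trend removed (Wnt10a edgeR adjusted p = 0.0594). Nkd1, Nkd2 and Notum encode inhibitors of the pathway. There were 6 falls and 1 rise adjusted over the list alone, and 9 falls and 5 rises with the replicate block. Camera did not call this list (adjusted p = 0.0521), but did with the replicate block, with the trend kept (0.014) or removed (0.0258), without bulk replicate 1 (0.0122) and without GFP replicate 2 (0.0272). With an estimated correlation it was not called (adjusted p = 0.399, and 0.42 with the block). Among 13 Hedgehog genes 2 fell and none rose. The ligand gene Shh fell, and had 99 and 282 counts in bulk and 2, 2 and 3 in sorted cells. Shh and the Wnt list gene Lef1 are also members of the hair matrix list, so these falls are not separate results. Adjusted over the list alone 4 fell, and with the replicate block 9 fell and 1 rose, or 7 and 3 with the trend removed. Camera called that list lower (adjusted p = 0.00716; adjusted p = 0.446 with an estimated correlation), but not without bulk replicate 2 (0.107) or with the length and GC trend removed (0.117).

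Of 15 Notch genes only Heyl was called, also adjusted over the list alone, falling by 3.84 ± 0.39. With the replicate block 6 fell and 3 rose, and the list was not called by camera (adjusted p = 0.132), while fry called it lower without the block (adjusted p = 0.0181) and not with it (0.111). With the block and the trend removed 4 fell and 2 rose. Among 20 genes of EGFR signalling Ereg and Spry4 fell by 3.54 ± 0.27 and 1.77 ± 0.33 and Epgn rose. With the length and GC trend removed and no block, no gene of this list was called higher, Epgn included. Spry4 was not called without bulk replicate 1, bulk replicate 2 or GFP replicate 2 (edgeR adjusted p = 0.0658, 0.223 and 0.0738). Epgn was not called without these libraries either (0.2, 0.0924 and 0.0545). Ereg, Areg and Epgn encode ligands of the same receptor family. Adjusted over the list alone Areg was a further rise. Over all genes it was not called by edgeR (adjusted p = 0.0751), but was by the DESeq2 Wald test, with no filter on low counts, and with the replicate block (4.07e-05), and not with the block and the trend removed (0.297). With the block 5 rose and 3 fell, or 2 and 4 with the trend removed, and camera did not call the list (adjusted p = 0.89). Its median was 0.03 and its mean -0.12. Among 20 BMP and TGF-beta genes Bambi fell by 1.11 ± 0.22 and Fst, a secreted inhibitor of activin, rose by 0.96 ± 0.20. Neither was called without bulk replicate 1, bulk replicate 2 or GFP replicate 2 (edgeR adjusted p = 0.175, 0.157 and 0.0965 for Bambi, and 0.206, 0.322 and 0.117 for Fst). There were 2 rises and 2 falls adjusted over the list alone, and with the replicate block 6 rose and 3 fell. Camera did not call this list (adjusted p = 0.0564), but did without GFP replicate 1 (0.0441), without GFP replicate 2 (0.0475) and with the length and GC trend removed (0.0377). With an estimated correlation the BMP list was not called (adjusted p = 0.353, and 0.512 with the block).

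With the same limits, the 10 largest rises included Epgn (ENSMUSG00000035020.12, 1.66 ± 0.32), the urokinase receptor gene Plaur (1.48 ± 0.28), the lipid droplet gene Hilpda (1.30 ± 0.23) and the stress-associated keratin gene Krt16 (1.19 ± 0.25). Ch25h, Mt2, Pxdc1, Pmp22 and Vps37b were also among them. The edgeR adjusted p of these 10 ran from 0.0159 for Hilpda to 0.044 for Mt2. With the length and GC trend removed Plaur, Hilpda, Pxdc1 and Vps37b stayed called, and Epgn did not (1.25 ± 0.42, edgeR adjusted p = 0.175). Of the 10, 1 was called without bulk replicate 1, 0 without bulk replicate 2, 6 without GFP replicate 1 and 2 without GFP replicate 2.

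Of 16 genes of the upper hair follicle and junctional zone, the niche that Lrig1 marks, Fst rose and no other was called, also adjusted over the list alone. Fst was not called without bulk replicate 1, bulk replicate 2, GFP replicate 1 or GFP replicate 2 (edgeR adjusted p = 0.206, 0.322, 0.0564 and 0.117), or with the length and GC trend removed (0.0545). Without GFP replicate 3, 2 genes of this list rose. With the replicate block 12 rose and 1 fell, and with the block and the trend removed 9 rose and 1 fell. The list median was 0.44, and camera called it higher (adjusted p = 0.0049; adjusted p = 0.353 with an estimated correlation). Plet1, another marker of this zone, was at 654 ± 168 CPM in bulk and 1174 ± 213 CPM in sorted cells (edgeR adjusted p = 0.185, 8.15e-06 with the block, and 0.0331 with the block and the trend removed). Nectin4 had a log2 change of -0.87 ± 0.24 (edgeR adjusted p = 0.101, 1.19e-07 with the block and the trend kept, and 0.0472 without GFP replicate 2).

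edgeR called none of 15 genes of basal layer adhesion and keratins, over all genes or adjusted over the list alone. At an unadjusted p under 0.05, 6 were higher, DESeq2 called 2 higher and limma-voom 0, and with the replicate block 8 rose and 1 fell, or 13 and 0 with the trend removed. The list median was 0.55, and camera called it higher (adjusted p = 4.13e-04; adjusted p = 0.353 with an estimated correlation). The basal keratin gene Krt14 was at 5874 ± 598 CPM in bulk and 11184 ± 1771 CPM in sorted cells (edgeR adjusted p = 0.202, and 1.96e-06 with the block and the trend kept). The laminin gene Lamb3 was at 316 ± 28.9 and 497 ± 25.7 CPM (edgeR adjusted p = 0.155, and 3.03e-04 with the block and the trend kept).

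Of 12 interfollicular basal genes the metallothionein gene Mt2 rose by 1.15 ± 0.26 and Dlx1 fell by 2.15 ± 0.37. Mt2 was not called without bulk replicate 1, bulk replicate 2, GFP replicate 1 or GFP replicate 2 (edgeR adjusted p = 0.301, 0.221, 0.101 and 0.13) or with the length and GC trend removed (0.236), and Dlx1 not without bulk replicate 2 (0.157). Without GFP replicate 3, 2 genes of this list rose. With the replicate block 8 rose and 1 fell, and adjusted over the list alone 5 rose and 1 fell. Camera called the list higher (adjusted p = 0.0049; adjusted p = 0.353 with an estimated correlation), but not without bulk replicate 1 (0.0519). edgeR called none of 18 bulge stem cell genes, over all genes or adjusted over the list alone. At an unadjusted p under 0.05, 3 were higher, DESeq2 and limma-voom called 0, and with the replicate block 5 rose and 1 fell. The bulge keratin gene Krt15 was at 4268 ± 156 CPM in bulk and 6537 ± 1065 CPM in sorted cells (edgeR adjusted p = 0.389, 5.37e-04 with the block, and 0.061 with the block and the trend removed). The list was higher by camera (adjusted p = 0.00547; adjusted p = 0.353 with an estimated correlation). Of 11 outer root sheath and companion layer genes Krt16 rose and Krt75 fell by 2.86 ± 0.42, the same 2 adjusted over the list alone. Krt16 was not called without bulk replicate 1, bulk replicate 2, GFP replicate 1 or GFP replicate 2 (edgeR adjusted p = 0.282, 0.117, 0.0633 and 0.1), or with the length and GC trend removed (0.0625). Without GFP replicate 3 there were 2 rises. The replicate block gave 7 rises and 1 fall, or 4 and 3 with the trend removed. Camera did not call the list (adjusted p = 0.209), but did without GFP replicate 3 (0.0351). With an estimated correlation the adjusted p was 0.571, and 0.646 with the block. Its median was 0.44 and its mean -0.00341.

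edgeR called none of 24 cell cycle genes, over all genes or adjusted over the list alone. At an unadjusted p under 0.05, 6 were higher, DESeq2 called 2 higher and limma-voom 0, and with the replicate block 9 rose and 2 fell, or 6 and 2 with the trend removed. Without GFP replicate 3, 1 fell. The mitotic kinase gene Cdk1 was at 21.6 ± 1.05 CPM in bulk and 35.0 ± 2.52 CPM in sorted cells (edgeR adjusted p = 0.0815, and 1.71e-05 with the block and the trend kept). Camera called the list higher (adjusted p = 0.00225; adjusted p = 0.353 with an estimated correlation). Of 21 antimicrobial and chemokine genes the alarmin gene Il33 rose by 0.85 ± 0.19 and no other was called. Il33 was not called without bulk replicate 1, bulk replicate 2, GFP replicate 1 or GFP replicate 2 (edgeR adjusted p = 0.154, 0.43, 0.0867 and 0.148), or with the length and GC trend removed (0.086). Without GFP replicate 3 the list had 5 rises. Adjusted over the list alone 8 rose and 2 fell, and with the replicate block 14 rose and 2 fell, or 10 and 2 with the trend removed. The list was higher by camera (adjusted p = 0.00169; adjusted p = 0.353 with an estimated correlation).

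Immediate early and dissociation genes, induced while tissue is taken apart, also lay higher in sorted cells, with a median of 0.36. edgeR called none of the 18, over all genes or adjusted over the list alone. At an unadjusted p under 0.05, 2 were higher, DESeq2 called 1 higher and limma-voom 0, and with the replicate block 9 rose, or 2 with the trend removed. Camera called the list higher (adjusted p = 0.0049; adjusted p = 0.353 with an estimated correlation), but not without bulk replicate 1 (0.0993). edgeR called none of 8 mitochondrially encoded genes, with 0 at an unadjusted p under 0.05 and 0 called by DESeq2 or limma-voom. The replicate block gave 3 falls and 1 rise, or 7 and 0 with the trend removed. Camera did not call the list (adjusted p = 0.745), but called it lower with the block and the trend removed (0.00202). With an estimated correlation the adjusted p was 0.923, and 0.822 with the block and the trend kept. All genes with the mitochondrial prefix, which are more than this list, held 1.812 to 2.486 percent of counts in bulk and 1.365 to 2.459 percent in sorted libraries.

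**Figure D3:**
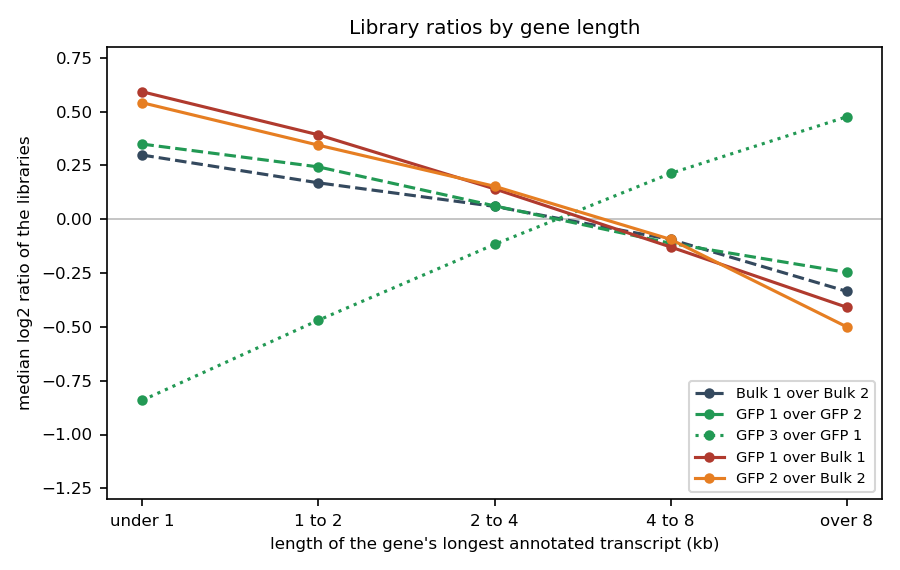
Median log2 ratio of 2 libraries (y axis) for genes grouped by the length of their longest annotated transcript in kb (x axis), each line a pair of libraries. GFP 1 over bulk 1 goes from 0.592 under 1 kb to -0.409 over 8 kb, bulk 1 over bulk 2 also falls with length, and GFP 3 over GFP 1 rises from -0.841 to 0.476.

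Leaving out single libraries moved the counts. In all, 523 genes were called without bulk replicate 1 and 480 without bulk replicate 2. The number called higher was 7 without bulk replicate 1, 1 without bulk replicate 2, 12 without GFP replicate 1, 11 without GFP replicate 2 and 96 without GFP replicate 3. Library ratios also followed gene length, within groups as well as between them. Spearman's rho across genes, which are not independent replicates, was -0.389 for bulk 1 over bulk 2 and -0.532 for GFP 1 over bulk 1.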

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

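Both settings with the length and GC trend removed were chosen after the data were seen, and the other alternatives before. More genes were called lower than higher in every setting. Among the changes below, causes were weighed only for the rise in calls with the replicate block. Total, higher and lower calls were 982, 27 and 955. They were 6692, 3040 and 3652 with the replicate block, 3701, 1281 and 2420 with the replicate block as a random effect (limma-voom), 5578, 1686 and 3892 with the replicate block with length and GC trend removed, and 1918, 258 and 1660 with no filter on low counts. DESeq2's Wald test called 1498 genes, 188 of them higher. Genes called higher numbered 10 with library size alone (where the median of all genes moved from 0.05 to -0.07), 2 in the test against a 1.5-fold change and 50 with the length and GC trend removed without a block, when 12 of the 27 were kept. Removing the trend moved the median of all genes from 0.05 to -0.05 without the block, and from 8.32e-05 to -0.112 with it. Leaving out 1 library gave 480 (without bulk replicate 2) to 1205 calls (without GFP replicate 3), 1 to 96 higher and 479 to 1109 lower. Where this left 1 bulk library, it was assumed to vary like the sorted ones. Lrig1 was called with the replicate block (0.45), the random effect (0.45, adjusted p = 0.0342) and the block with the trend removed (0.56). Of 27 lists, camera called 12 lower and 7 higher; with an estimated correlation it called 0 (6 at an unadjusted p under 0.05, smallest adjusted p = 0.0954), and fry called 8, all lower. The block moved no camera call at the preset correlation besides Wnt signalling and endothelial genes. With it fry called only Wnt signalling (0.0437) and none of its 8. Camera at an estimated correlation had little power here, with 3 residual degrees of freedom and 1 with the block. With the block its adjusted p was 0.42 both for the hair matrix list (17 of 17 lower) and for the bulge list (block median 0.16). Such a result cannot tell a changed list from an unchanged one. Of 130 named genes 52 gained a call with the block. The signs that turned belonged to results not called without a block. Over single libraries left out, log2 changes ran from -0.004482 to 1.386 for mt-Nd3, -0.08228 to 0.9003 for mt-Nd6, -0.2168 to 0.6311 for mt-Nd5 and -0.8297 to 0.118 for the unnamed ENSMUSG00000119584. With the block they were -0.03657 for mt-Nd6, -0.1806 for mt-Nd5 and 0.08468 for ENSMUSG00000119584. With the random effect mt-Nd5 was at -0.04948. With the trend removed mt-Nd6 was at -0.06946 and mt-Nd5 at -0.04781. With block and trend removed Tnni2 was at -0.03716, and mt-Nd6 and mt-Nd5 were called lower (-0.7204 and -0.4854). Adjusted p of the EGFR list, whose direction turned, was 0.526 (fry), 0.99 (trend removed) and 0.441 to 0.999 with 1 library left out. For mitochondrial genes it was 0.399 (block), 0.412 (trend removed), 0.00202 (block and trend removed, lower) and 0.179 to 0.75 with 1 library left out. For skeletal muscle it was 0.359 to 0.922 with 1 library left out, and for Merkel and Schwann cells 0.833 (block and trend removed). The EGFR list's median also turned with library size alone (-0.09). Simulated 2-fold changes were mostly missed without a block (7.292 percent recovered). That simulation held fewer changed genes, and so a stricter cutoff, than the data, and power in the data was not measured. A gene not called is not shown to be unchanged.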

Other observations

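The gene families, the length trend and its removal, and the comparison of the junctional and basal lists were chosen after the results were seen, while the edgeR test, DESeq2, limma-voom, the replicate block and leaving out libraries were fixed earlier. Keratin-associated proteins, which cross-link keratin in the hair shaft, summed to 342 and 225 CPM in bulk replicates 1 and 2 and to 3.05, 2.11 and 3.07 CPM in the 3 sorted libraries, and 27 of 32 fell with edgeR, or 12 of 33 without bulk replicate 1. Late cornified envelope genes summed to 91.0 and 28.2 CPM in bulk and 2.44, 0.784 and 4.23 CPM in sorted libraries, with 8 of 13 falling, or 1 of 14 without bulk replicate 1 and 4 of 13 without GFP replicate 1. Small proline-rich genes, also part of the cornified envelope, summed to 914 and 960.5 CPM in bulk and 1007, 1132 and 667 CPM in sorted libraries. Of these 8, 2 fell, 0 without bulk replicate 1, 1 without bulk replicate 2, GFP replicate 1 or GFP replicate 2, and 6 with the replicate block and the length and GC trend removed. edgeR called none of 81 cytosolic ribosomal protein genes, with 2 higher at an unadjusted p under 0.05, 1 called higher by DESeq2 and 0 by limma-voom. At that unadjusted p 70 of 80 were higher without GFP replicate 3, 6 of 82 without bulk replicate 1, and 1 without each other library. The replicate block gave 77 rises, and 26 rose and 1 fell once the length and GC trend was also removed. All 13 late cornified envelope genes fell with the block.

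Library ratios differed along gene length. If the sorted and the bulk population were the whole source, the 2 bulk libraries would not differ, but their ratio had a Spearman rho of -0.389 with length across genes, which argues against it. Among genes not called, the ratio of GFP 3 to GFP 1 had a rho of 0.598, so the trend is also present inside the sorted group. RNA or library quality may be the source, but each library of a group carries its own title number and no quality value is in the labels, so library and animal cannot be told apart.

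Without a block 27 genes were called higher and 955 lower, and with the replicate block the split was 3040 to 3652. Whether GFP replicate 3 alone hides the rises stays open. Without it and without a block 96 genes were called higher (1654 against 796 at an unadjusted p under 0.05). The simulated fit without a block recovered 7.292 percent of 2-fold changes, but it held all 5 libraries. Power without GFP replicate 3 was not simulated, so the count of 96 cannot decide the question. GFP 3 was also the only library with abundant Xist, so sex, animal and library cannot be told apart for it. The length trend alone does not account for all blocked rises: with it removed 1686 genes were called higher, 1290 of them among the 3040, although in simulation a trend left in place produced most of the blocked calls. That simulation counted the whole trend as false, so its share of false calls does not carry over to these data. Differences between animals that both libraries of an animal share could account for part of it: the bulk and the sorted differences between numbers 1 and 2 correlated across genes after the trend was removed (r = 0.466). This rests on 2 pairs and on reading title numbers as animals.

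Junctional zone and basal layer lists both had medians above 0 in sorted cells. Neither was called by camera with an estimated correlation (adjusted p = 0.353 for both) or by fry (adjusted p = 0.155 and 0.0931). A candidate explanation is that the sort enriched the junctional zone over other basal cells. The junctional list's median, without Lrig1, minus the basal list's was -0.1067 (95% bootstrap interval over genes, not libraries, -0.1979 to 0.1839, permutation p = 0.275, two-sided) and -0.1082 with the replicate block and the trend removed, but 0.2287 with the replicate block (-0.1021 to 0.4936), 0.0579 with the random effect, 0.0867 without bulk replicate 1 and 0.2425 without GFP replicate 3. With the trend removed and no block it was -0.124 (permutation p = 0.0258), so the sign depends on the setting and whether the junctional zone was enriched cannot be told apart from no enrichment. A loss of cornified, hair and non-epithelial cells from the sorted fraction would raise both lists alike, and was not tested separately.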
